A study of Homo sapiens with 7 samples.

How the data were processed

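Gene expression was measured on 7 Agilent arrays with 2 colours. Each array compared RNA of treated cells, labelled with Cy5, with RNA of control cells of the same line, labelled with Cy3, per the labels. On 4 arrays the treated cells were PC3 cells, a line derived from a human prostate cancer, carrying a short hairpin RNA (shRNA) against ETV4, and the control cells carried an shRNA against luciferase. Each of the 2 shRNA sequences had 2 arrays. On 3 arrays the treated cells were RWPE-1 cells, an immortalised line of human prostate epithelium, carrying an expression vector for ETV4 with a Flag tag, and the control cells carried the empty vector. The labels call the arrays of a group biological replicates and give no further detail of the cultures, so p-values measure the spread between these samples. Per the labels, no array had the dyes swapped, so a dye effect of a probe stays in each ratio. Whether the PC3 arrays shared 1 preparation of control RNA is not given in the sources used here.

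Per the labels' protocols, total RNA was primed with an oligo-dT T7 primer and amplified into dye-labelled cRNA with spike-in controls. The deposited scanner files hold, per the file headers, the intensity of each spot as the mean brightness of its pixels in each channel and the median brightness of the local background. They also hold the log10 ratio of the processed Cy5 over the processed Cy3 signal of each spot. Per the file headers, the software had subtracted a fitted spatial background and normalized the dyes by a linear and a lowess step for that ratio. Other deposited columns hold marks per spot, with values other than measurements, for signal above background, outlier pixels, saturation and control spots. The file headers name Agilent Feature Extraction 9.5.1.1 for the 3 arrays of slide 1 and 10.1.1.1 for the 4 arrays of slide 2, while the submitters' processing notes name version 10.5. Slide 1 held the first shRNA replicate 1 and both replicates of the second shRNA and was scanned with an extended dynamic range. Slide 2 held the first shRNA replicate 2 and the 3 RWPE-1 arrays. In the deposited table of the whole series, the median of each of the 7 columns was 0, and all 45015 values of each column equalled the log10 ratio of that array's scanner file within a tolerance of 1e-06. Its scale, centring and direction are therefore those of that ratio, and none of the 3 stays unknown.

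Each array held 45015 spots, of which 1639 were control spots and 43376 carried 41000 different probes of 60 bases. Background was corrected with normexp at an offset of 50 on the mean and background intensities, and each array was normalized by loess with a span of 0.3 and control spots at weight 0. Control spots and spots marked as outliers in either channel were then left out, spots of 1 probe were averaged, and 169 probes left without a usable spot on some array were not tested. A probe was kept where it was well above background in at least 1 channel on at least 2 of the 7 arrays, which left 31714 probes. Names came from the accession of each probe, matched without versions to a table of RefSeq genes for 23958 probes, from a current symbol for 2755 and from an older symbol for 1032, and 13255 probes without a match kept the name in the file. The brightest probe stood for a gene, which gave 23205 genes, 15166 of them with a symbol. Probe coordinates are those of build hg18 in the scanner files of slide 2. Where a named gene's probe was not well above background in a channel on every array of a group, its ratio in that group is not given. No genome sequence was used, so exons and untranslated regions are not given.

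Log2 ratios, computed here from the deposited intensity values, were tested with limma: lmFit with 1 coefficient for each of the 3 groups over all 7 arrays, eBayes, and the Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. The fit had 4 residual and 3.21 prior degrees of freedom. The contrasts were each shRNA against its control, the mean of both shRNAs, the first minus the second shRNA, ETV4 expression in RWPE-1, and the RWPE-1 value minus the mean knockdown value. Groups, designs, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named ETV4, ETV1 and ETV5; for the mean knockdown and the RWPE-1 contrasts the 10 highest and 10 lowest ratios among genes with a symbol that passed the test with 1 direction on every array; for each shRNA the 5 highest and 5 lowest; and for each gene list up to 4 members that passed, or the 2 with the largest ratios where fewer than 2 passed. Some of these genes are not reported here, and the list counts and medians include them. It also took the 5 highest and 5 lowest genes differing between the shRNAs and up to 10 genes called in opposite directions in the 2 lines, and none passed. For the RWPE-1 minus knockdown contrast, opposite signs of the means in the 2 lines took the place of 1 direction.

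The 25 gene lists held 421 genes, of which 24 had no tested probe. They were ETS family factors, RAS/ERK targets, the AP-1 family, extracellular proteases, adhesion genes, mesenchymal, epithelial, basal and luminal prostate markers, proliferation genes, interferon response genes, inflammatory genes, p53, TGF-beta and WNT targets, hypoxia, cholesterol, unfolded protein response and heat shock genes, angiogenic factors, markers of fibroblasts, leukocytes, endothelium and neuroendocrine cells, and ribosomal protein genes. They were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over the lists. Another 4 lists (aminoacyl-tRNA synthetases, trefoil factors and mucins, proteasome subunits and circadian clock genes) were written after the data were seen.

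The procedure was tested on data simulated from real intensities of 23205 genes. In the simulated mean knockdown it called 52.2% of 67 genes changed 1.5-fold, 92.5% of 67 at 2-fold and 95.5% of 66 at 4-fold. Of 181 calls 16 were false (8.84%). In simulated RWPE-1 it called 31.3%, 97.0% and 98.5% of as many, with 9 of 160 calls false (5.63%). Real RWPE-1 arrays varied more (SD 0.350, PC3 0.208), so these rates need not hold. Camera called the simulated list of 21 members shifted by 0.5 in log2 (adjusted p = 4.93e-28, or 0.00617 with an estimated correlation). It also called 1 other of 25.

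Between 66.2% and 75.1% of spots were well above background in Cy5 and between 63.7% and 74.4% in Cy3, and the number of arrays limits the precision. Alternatives planned in advance were no background subtraction, the deposited log10 ratio, the deposited series table, median centring, scaling or Aquantile between arrays, no filter or a filter on all 7 arrays, all probes or the mean of the probes, separate fits of the cell lines, array weights, the slide and the replicate number as blocks, an intensity trend, a 1.5-fold minimum and leaving out each array. The slides alone, the reading of the slide block at either slide, a threshold of 0.10 and turning the sign of the RWPE-1 arrays were added after the data were seen. The computations used R 4.3.3, limma 3.58.1 and the data.table package 1.17.8, and the figures matplotlib 3.10.9.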

Results

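The series measured transcript levels after ETV4, an ETS family transcription factor, was lowered in PC3 prostate cancer cells and after a tagged ETV4 was introduced into RWPE-1 prostate epithelial cells. Of the 7 arrays, 4 compared an ETV4 shRNA with a luciferase shRNA in PC3, 2 arrays for each of 2 shRNA sequences. The other 3 compared RWPE-1 cells carrying the ETV4 vector with cells carrying the empty vector. Each value is the log2 ratio of treated over control cells on 1 array, so a positive value means more transcript in the treated cells. Each array read 41000 probes, of which 31714 passed the filter on dim probes and stood for 23205 genes. The arrays lay on 2 slides, and results are given with the slide as a block and within a slide.

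ETV4 was lower on each of the 4 PC3 arrays with an ETV4 shRNA. Its 2 probes lie on the minus strand of chromosome 17 (hg18). The first, at 38961492 to 38961551, had the sequence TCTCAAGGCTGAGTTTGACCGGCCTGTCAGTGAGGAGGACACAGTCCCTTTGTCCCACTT. It gave log2 ratios of -1.36 and -1.76 with the first shRNA and -1.41 and -1.33 with the second. The other, at 38961317 to 38961376, had the sequence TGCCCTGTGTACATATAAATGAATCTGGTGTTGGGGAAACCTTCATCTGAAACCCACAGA. It stood for the gene as the brighter probe and gave -1.34, -1.85, -1.26 and -1.31 in the same order. Over the 4 arrays this probe averaged -1.44 (SE 0.15, SD 0.27, n = 4), or 36.9% of the control (limma adjusted p = 0.00375). The first probe averaged -1.46 (SE 0.10, SD 0.20, n = 4), or 36.2%. On the 3 RWPE-1 arrays labelled ETV4 the probes lay on opposite sides of 0. The first gave 0.12, 0.44 and 0.56 (mean 0.37, SD 0.23, n = 3, adjusted p = 0.111). The other gave -1.08, -1.17 and -0.35 (mean -0.87, SD 0.45, n = 3, adjusted p = 0.0572). Without RWPE-1 replicate 3 the second probe averaged -1.12 and passed (adjusted p = 0.0144). One ETV4 probe thus ran against the label of the RWPE-1 arrays, which bears on every direction drawn from them. Both probes were well above background in both channels on all 7 arrays. In the mean knockdown the gene's call held in 17 of 17 alternatives, with log2 ratios of -1.84 to -1.23 and adjusted p of 0.00162 to 0.0423. It was -1.57 with the slide as a block (adjusted p = 0.0336) and -1.31 on slide 1 alone.

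ETV1 and ETV5 are the closest relatives of ETV4 within the ETS family. ETV1 rose in the mean of the PC3 arrays by 1.19 on the log2 scale (SE 0.10, SD 0.26, n = 4, adjusted p = 0.00262; chromosome 7, 13897562 to 13897621). Its other probe gave 0.95. The ETV1 ratio was 1.16 with the slide block (adjusted p = 0.0355) and 1.22 on slide 1 alone. ETV5 stood at 0.56 in PC3 (SE 0.19, SD 0.23, n = 4, adjusted p = 0.0790; chromosome 3, 187247241 to 187247300). It passed with median centring (0.77, adjusted p = 0.0273) and stood at 0.61 on slide 1 alone. On the RWPE-1 arrays labelled ETV4, ETV1 stood at -0.12 (SD 0.27, adjusted p = 0.557) and ETV5 at -0.63 (SD 0.62, adjusted p = 0.134), n = 3 each.

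**Figure D1:**
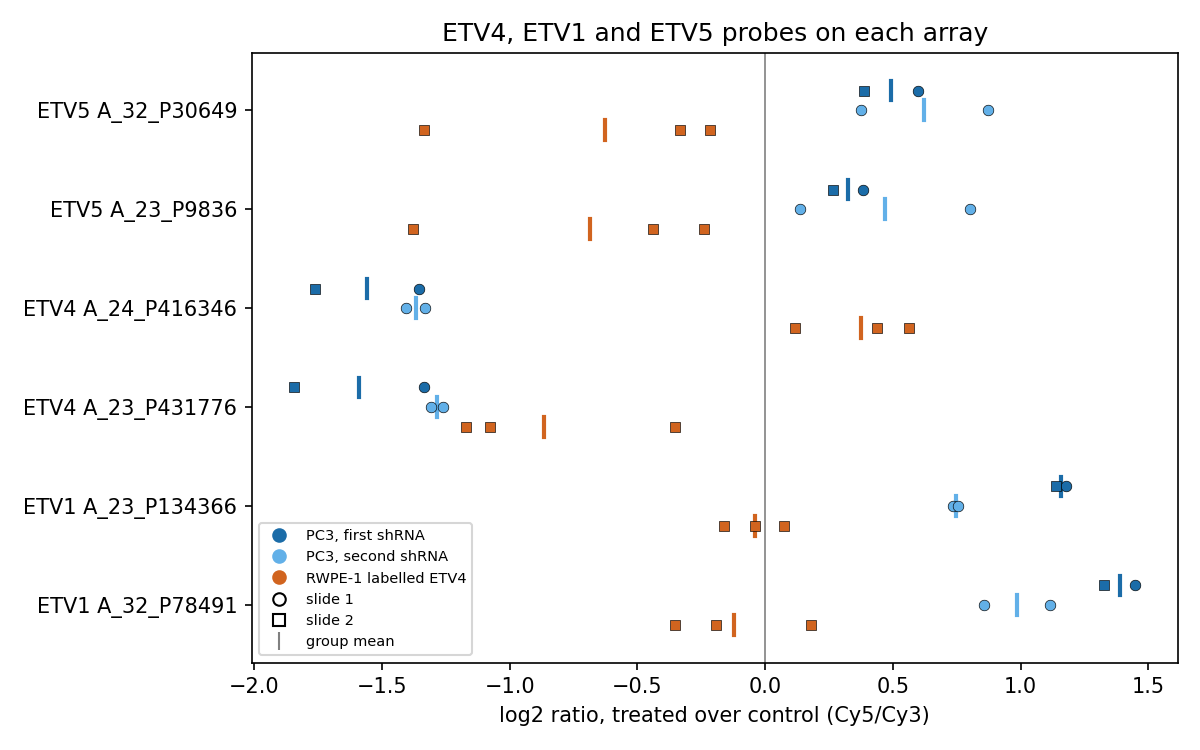
Log2 ratio of treated over control cells (horizontal axis) for the 6 probes of ETV4, ETV1 and ETV5 (vertical axis); each point is 1 array, with circles for slide 1, squares for slide 2, dark blue for the first shRNA, light blue for the second, orange for the RWPE-1 arrays labelled ETV4, and vertical ticks for group means. The 4 PC3 arrays lie between -1.85 and -1.26 on both ETV4 probes, while the RWPE-1 arrays lie between 0.12 and 0.56 on the first and between -1.17 and -0.35 on the second.

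The first shRNA changed 1178 genes against its control, 614 of them higher and 564 lower, with 184 higher and 92 lower by at least 2-fold (n = 2). The higher share was 52.1%, against 82.4% of 624 genes with median centring. The highest were LXN, an inhibitor of carboxypeptidases (2.86, SE 0.18, adjusted p = 0.00522), MMP13, a collagenase (2.79, adjusted p = 0.000813), and ALDH2, the mitochondrial aldehyde dehydrogenase (2.35, adjusted p = 0.0118). NDRG1, a gene induced by stress and hypoxia, and HPGD, which inactivates prostaglandins, stood at 2.26 each (adjusted p = 0.0408 and 0.0160). The lowest were NAV3, a microtubule-associated protein (-2.12, adjusted p = 0.0274), and BIRC3, an inhibitor of apoptosis (-2.10, adjusted p = 0.0118). They were followed by EFEMP1, an extracellular matrix protein (-1.83, adjusted p = 0.0351), IL23A, a subunit of interleukin 23 (-1.76, adjusted p = 0.0397), and DDAH1, which degrades dimethylarginine (-1.71, adjusted p = 0.0118). ETV4 itself stood at -1.59 (SE 0.21, adjusted p = 0.0184) and ETV1 at 1.39 (SE 0.15, adjusted p = 0.0127). ETV5 at 0.49 did not pass (adjusted p = 0.334). With the slide as a block 381 genes passed, and 7 of these 10 genes did. Leaving out either array of this shRNA left 1 gene in all, and ETV4 and ETV1 lost their calls. Leaving out replicate 1 or 2 of the second shRNA left 209 or 210 genes, and leaving out RWPE-1 replicate 1 gave 1898.

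With the second shRNA, 181 genes rose and 133 fell, 71 and 43 of them by at least 2-fold (n = 2). The higher share was 57.6%, against 85.1% of 3460 genes with median centring. LXN (2.94, SE 0.18, adjusted p = 0.00644) and MMP13 (2.83, SE 0.12, adjusted p = 0.000745) were again the highest. They were followed by IL33, a cytokine (2.19, adjusted p = 0.0188), MKX, a homeobox factor (1.95, adjusted p = 0.0381), and NEBL, an actin-binding protein (1.90, adjusted p = 0.0416). NAV3 (-2.08, adjusted p = 0.0444) and BIRC3 (-2.07, adjusted p = 0.0188) were the lowest. They were followed by TFPI2, a serine protease inhibitor (-1.90, adjusted p = 0.0439), DAW1, of cilia (-1.64, adjusted p = 0.0123), and FAM111B, a serine protease (-1.61, adjusted p = 0.0353). ETV4 stood at -1.28 (SE 0.21, adjusted p = 0.0444), ETV1 at 0.99 (SE 0.15, adjusted p = 0.0360) and ETV5 at 0.62 (adjusted p = 0.220). With the slide as a block 1 gene passed in all, and ETV4 (-1.54, adjusted p = 0.549) and ETV1 (0.93, adjusted p = 0.601) lost their calls. On slide 1 alone, which holds both arrays of this shRNA, 3304 genes passed and all 10 named genes did. Limma called 0 genes without either array of this shRNA, against 5281 at an unadjusted p under 0.05 with all arrays. Leaving out either array of the first shRNA left 12, and leaving out RWPE-1 replicates 1, 2 and 3 gave 951, 644 and 122.

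Genes changed by 1 shRNA tended to change with the other. Of the genes called with each, 140 rose with both (4.79 expected from independent lists) and 95 fell with both (3.23 expected), and 0 were called in opposite directions. Across genes, which are not independent replicates, the shRNAs correlated at r = 0.819 (covariance 0.101). In 20 simulations of unchanged cells with 1 shared control and no dye effect, r was 0.501 (covariance 0.0155). The sign agreed for 77.0% of genes, against 66.7% there. Whether the control RNA was shared is unknown, and a dye effect would raise this agreement. In the direct test of the first minus the second shRNA, limma called 0 genes (smallest adjusted p = 1.00). At an unadjusted p under 0.05 there were 568, where 1160 were expected by chance. The pooled spread includes the RWPE-1 arrays, which varied more (SD 0.350, PC3 0.208), so this test may be too strict. Each alternative run for this difference also called 0 (slide 2 alone, which holds no array of the second shRNA, has no such test).

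Averaged over both shRNAs, 2279 genes rose and 2255 fell in PC3 (n = 4), 164 and 116 of them by at least 2-fold. The higher share was 50.3%, against 79.7% of 5264 genes with median centring. LXN rose 7.46-fold (log2 ratio 2.90, SE 0.13, SD 0.26, adjusted p = 0.000608; chromosome 3, 159867172 to 159867498) and MMP13 rose 7.01-fold (2.81, SE 0.08, SD 0.15; chromosome 11, 102320236 to 102320295; adjusted p = 6.51e-05). The next highest were NPTX1, a neuronal pentraxin (2.11, SE 0.32), TFF3, a trefoil factor (1.98, SE 0.25), and ALDH2 (1.95, SE 0.16). They were followed by S100P, a calcium-binding protein (1.94, SE 0.45), RDH10, a retinol dehydrogenase (1.93, SE 0.19), IL33 (1.92, SE 0.15), NEBL (1.87, SE 0.21) and SCARA5, a scavenger receptor (1.79, SE 0.10). Their adjusted p lay between 0.00128 for SCARA5 and 0.0252 for S100P. NAV3 fell the most, to a log2 ratio of -2.10 (SE 0.24, adjusted p = 0.00472), followed by BIRC3 (-2.09, SE 0.14, adjusted p = 0.00128), and IL13RA2, a receptor of interleukin 13 (-1.88, SE 0.31). Next came IL23A (-1.74, SE 0.24), TFPI2 (-1.68, SE 0.22) and ADAMTS6, a metalloprotease (-1.67, SE 0.27). The last of the 10 were DTL, of a ubiquitin ligase (-1.66, SE 0.29), RRM2 (-1.65, SE 0.30, with 1 of its 2 other probes in the opposite direction), SCEL, a protein of the cornified envelope (-1.63, SE 0.23), and DDAH1 (-1.61, SE 0.12). The largest adjusted p among these was 0.0128, for RRM2.

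Each of these 20 genes kept its sign in the 17 alternatives run for named genes, except that 1 of them was not tested where signal on all 7 arrays was required. With the slide as a block 352 genes passed in all, as without the first shRNA replicate 1, since the block rests on that array and its replicate on the other slide. On slide 1 alone 6401 passed. Leaving out the second shRNA replicate 1 gave 355 genes, the first shRNA replicate 2 gave 1985 and the second shRNA replicate 2 gave 1714. Of the 20 named genes 12 passed with the block. The 8 that did not were NPTX1 (1.90, adjusted p = 0.0703), S100P (2.15, adjusted p = 0.103), IL13RA2 (-2.06, adjusted p = 0.0611), IL23A (-1.73, adjusted p = 0.0611), ADAMTS6 (-1.48, adjusted p = 0.0776), DTL (-1.26, adjusted p = 0.0697), RRM2 (-1.23, adjusted p = 0.0742) and SCEL (-1.48, adjusted p = 0.0620). Without the second shRNA replicate 1 the same 8 genes and TFPI2 (-1.499, adjusted p = 0.0558) missed the threshold. S100P missed it without the first shRNA replicate 2 (1.73, adjusted p = 0.111) and, with IL13RA2 (-1.69, adjusted p = 0.0537), without the second shRNA replicate 2 (1.99, adjusted p = 0.0942). Another probe stood for SCARA5 with the deposited log10 ratio (0.21, adjusted p = 0.304) and where signal on all 7 arrays was required (0.22, adjusted p = 0.147).

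**Figure D2:**
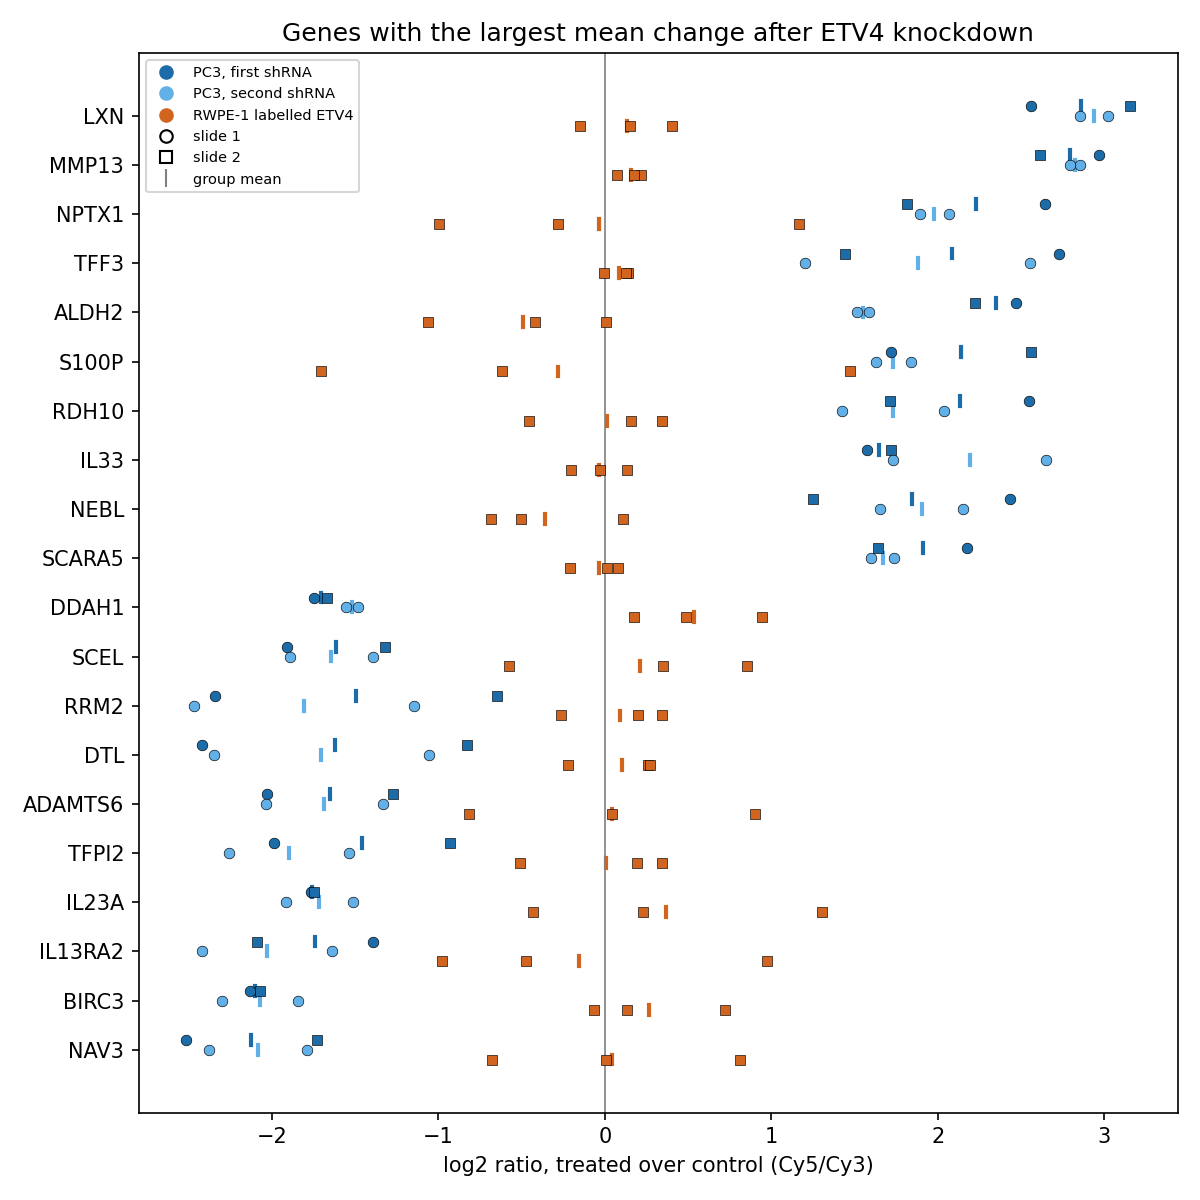
Log2 ratio of treated over control cells (horizontal axis) for the 10 genes that rose most and the 10 that fell most in the mean of both ETV4 shRNAs in PC3 (vertical axis); each point is 1 array, with symbols and colours as in the figure of the ETV probes. LXN averaged 2.90 and NAV3 -2.10 over the 4 PC3 arrays, against 0.14 and 0.05 over the 3 RWPE-1 arrays.

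Genes of cell division fell with ETV4 knockdown. Of 29 proliferation genes measured, 16 fell, 0 rose and 13 did not pass, and 21 fell when adjusted over the list alone. RRM2 and TYMS, which supply deoxynucleotides, stood at -1.65 and -1.48, MCM7, a subunit of the replicative helicase, at -1.13, and CDC25A, a phosphatase that activates cyclin-dependent kinases, at -1.12. The list's median was -0.71 (camera adjusted p = 3.13e-10, and adjusted p = 0.863 with an estimated correlation), -0.59 with the slide block, -0.78 on slide 1 alone and -0.35 with median centring. TYMS stood at -0.91 without the first shRNA replicate 1 and at -0.95 without the second shRNA replicate 1 (adjusted p = 0.263 each).

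Genes of the unfolded protein response rose. Of 14 measured, 7 rose, 0 fell and 7 did not pass, and 11 rose when adjusted over the list alone. They included the chaperone cofactor DNAJB9 (1.26), SEL1L (1.00) and HERPUD1 (2.14-fold), which serve degradation at the endoplasmic reticulum, and the stress factor DDIT3 (1.02). The median was 0.81 (camera adjusted p = 8.92e-05, and adjusted p = 0.863 with an estimated correlation), 0.64 with the slide block, 0.93 on slide 1 alone and 1.22 with median centring. Without the first shRNA replicate 1, DNAJB9 stood at 0.69 (adjusted p = 0.136), HERPUD1 at 0.63 (adjusted p = 0.0650) and SEL1L at 0.65 (adjusted p = 0.106). Without the second shRNA replicate 2, DDIT3 stood at 0.62 (adjusted p = 0.151).

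Of 21 type I interferon response genes, 6 rose, 0 fell and 15 did not pass, and 7 rose when adjusted over the list alone. IFI27 (1.18) and the antiviral GTPase MX1 (1.17) led, with IRF9, a factor of interferon signalling (1.11), and OAS1, a sensor of double-stranded RNA (0.85). The median was 0.55 (camera adjusted p = 0.00815, and adjusted p = 0.863 with an estimated correlation), 0.47 with the slide block and 0.57 on slide 1 alone. On single arrays it was 0.22 and 0.06 with the first shRNA and 0.94 and 0.46 with the second. The difference between the shRNAs was not tested for lists. Of 16 hypoxia and glycolysis genes, 5 rose, 0 fell and 11 did not pass, and 6 rose when adjusted over the list alone. Examples were NDRG1 (1.53), the mitochondrial protein BNIP3 (0.83), lactate dehydrogenase A (LDHA, 0.60) and the glucose transporter SLC2A1 (0.54). Their median was 0.41 (camera adjusted p = 0.00233, and adjusted p = 0.863 with an estimated correlation), 0.49 with the slide block, 0.25 on slide 1 alone and 0.69 with median centring. On single arrays it was 0.45 and 1.00 with the first shRNA but 0.13 and -0.04 with the second. Without the first shRNA replicate 2 the median was 0.24 (adjusted p = 0.0506) and LDHA stood at 0.34 (adjusted p = 0.130).

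Cholesterol biosynthesis genes were lower, except that with median centring the list's median was 0.02 while the test's direction stayed down (adjusted p = 0.922). Of 16 measured, 4 fell, 0 rose and 12 did not pass, and 5 fell when adjusted over the list alone. The enzymes CYP51A1 (-0.61), DHCR7 (-0.59) and SQLE (-0.51) were among those that passed. DHCR7 passed in 7 of 17 alternatives (values of -0.78 to -0.08, adjusted p up to 0.716) and SQLE in 9 (-0.65 to -0.04, adjusted p up to 0.833). The median was -0.23 (camera adjusted p = 0.0108, and adjusted p = 0.863 with an estimated correlation), -0.16 with the slide block (adjusted p = 0.0783) and -0.37 on slide 1 alone. Leaving out the first shRNA replicate 1 (-0.16, adjusted p = 0.0797) or the second shRNA replicate 1 (-0.07, adjusted p = 0.296) ended the call. The median was -0.37 without the first shRNA replicate 2 and -0.42 without the second shRNA replicate 2.

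Ribosomal protein genes rose: 22 of 28 over all genes, with 0 lower and 6 not passed, and 26 when adjusted over the list alone. RPS2 stood at 0.90, RPLP1 at 0.89 and RPS18 at 0.86. The median was 0.50 (camera adjusted p = 5.11e-13, and adjusted p = 0.863 with an estimated correlation), 0.47 with the slide block, 0.52 on slide 1 alone, 0.27 with the deposited log10 ratio and 1.30 with median centring. Random lists of genes as bright as these had a median of 0.41, and the 100 brightest genes one of 0.50.

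The remaining lists were not called in the mean knockdown over all arrays, though alternatives called 2 of them, the inflammatory and the heat shock list. Of 24 ETS family factors, 4 rose and 2 fell (6 and 5 when adjusted over the list alone), among them ETV1, the epithelial factor ELF3 (0.78), ELF1 (0.56) and ETV4. Their median of 0.01 and mean of 0.02 were above 0 and the test's direction was down (adjusted p = 0.941). Of 22 RAS/ERK targets, 3 rose and 5 fell (5 and 5 over the list alone), with a median of 0.06 (adjusted p = 0.848). The proto-oncogene MYC stood at -0.84 (1 of its 2 other probes in the opposite direction), the feedback inhibitors SPRY2 and SPRY4 at 0.79 and 0.53, and the growth factor HBEGF at -0.68. Of 11 AP-1 genes, JUNB (0.51) and JUND (0.35) rose and 0 fell, also when adjusted over the list alone (median 0.16, adjusted p = 0.701). Among 20 extracellular proteases and their inhibitors, 5 rose and 3 fell by both adjustments, over all genes and adjusted over the list alone (median 0.04, adjusted p = 0.845). The collagenases MMP13 (2.81) and MMP1 (2.83-fold) and the stromelysin MMP10 (0.93) rose, and SERPINB2, an inhibitor of plasminogen activators, fell (-1.57). Among 21 adhesion genes, 2 rose and 3 fell by both adjustments (median 0.06, adjusted p = 0.846), with the integrin ITGA1 at 1.17 and the hyaluronan receptor CD44 at -0.65.

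Markers of cell state went both ways in PC3. Of 14 mesenchymal markers, S100A4 (0.62) and fibronectin (FN1, 0.54) rose and the repressor SNAI2 (-0.87) fell, the same counts when adjusted over the list alone (median 0.15, adjusted p = 0.310). Of 18 epithelial markers, 4 fell and 0 rose by both adjustments. They were the adhesion molecule EPCAM (-0.90), the keratins KRT8 (-0.77) and KRT7 (-0.39) and the junction protein TJP1 (-0.46), with a median of -0.15 (adjusted p = 0.138). KRT7 passed in 5 of 17 alternatives and stood at -0.03 with median centring (adjusted p = 0.900) and at -0.26 without the first shRNA replicate 2 (adjusted p = 0.222). Of 18 basal and squamous markers, KRT15 (0.65) rose and SFN (-0.50) fell, also when adjusted over the list alone (median 0.06, adjusted p = 0.829). Of 13 luminal prostate and androgen response genes, 3 rose and 2 fell (4 and 3 over the list alone), with NDRG1 at 1.53, the homeobox factor HOXB13 at 1.00 and STEAP1 at -0.81 among them. The median of 0.01 and the mean of 0.14 were above 0 while the test's direction was down (adjusted p = 0.930).

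Among signalling lists, 2 of 20 inflammatory genes fell and 0 rose by both adjustments, TNFAIP3 (-1.23) and NFKBIA (-0.79), both inhibitors of NF-kB (median -0.21, adjusted p = 0.0521). The list was called as lower with no background subtraction (-0.21, adjusted p = 0.0448), the deposited log10 ratio (-0.50, adjusted p = 0.0115) and median centring (-0.31, adjusted p = 0.00670). On slide 1 alone its median was -0.71. It was also called without the first shRNA replicate 2 (-0.24, adjusted p = 0.0259), the second shRNA replicate 2 (-0.31, adjusted p = 0.0171), or RWPE-1 replicate 1 or 2 (-0.21 each, adjusted p = 0.0212 and 0.0201). Of 16 p53 targets, the apoptosis gene BBC3 rose (0.40) and the death receptor FAS (-0.91) and the kinase PLK3 (-0.68) fell (median 0.07, adjusted p = 0.846). BBC3 passed in 7 of 17 alternatives, with values of 0.16 to 1.14 and adjusted p of 0.00151 to 0.338. Adjusted over the list alone, 3 rose and 2 fell. Of 15 TGF-beta targets, 3 fell and 0 rose (2 higher and 3 lower over the list alone), among them TGFBI (-0.76) and TGFB2 (-0.57). Their median was 0.07, whereas the mean of -0.04 and the test pointed down (adjusted p = 0.848). Of 12 WNT targets, 2 rose and 3 fell by both adjustments (median -0.05, adjusted p = 0.846). MYC stood at -0.84 and cyclin D1 (CCND1) at -0.43, but 0.12 with median centring. SP5 and NKD2 stood at 0.53 each, and their other probes (2 of 2 and 1 of 1) ran in the opposite direction. The heat shock list of 9 had 1 gene that fell by both adjustments, the mitochondrial chaperone HSPD1 (-0.52, but 0.32 with median centring). HSP90AA1 stood at -0.61 (adjusted p = 0.0866), and the median was -0.22 (adjusted p = 0.110), but 0.32 with median centring (adjusted p = 0.245). The list was called as lower with the deposited log10 ratio (-0.39, adjusted p = 0.0331), and its median was -0.33 on slide 1 alone. Without the first shRNA replicate 2 it stood at -0.33 and without the second shRNA replicate 1 at -0.32. Of 16 angiogenic factors, IGFBP3 rose (0.74) and CCN1 fell (-0.76), and 1 rose and 0 fell when adjusted over the list alone (median 0.20, adjusted p = 0.290). CCN1 passed in 10 of 17 alternatives, with values of -1.07 to -0.03 and adjusted p of 0.00577 to 0.939, the value nearest 0 with median centring.

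Markers of other cell types were not called in PC3. Of 8 fibroblast markers, COL6A3 rose (0.48) and LUM fell (-0.73), and 2 rose and 1 fell when adjusted over the list alone (median 0.12, adjusted p = 0.694). None of 5 leukocyte, 6 endothelial or 5 neuroendocrine markers passed, over all genes or adjusted over the list alone. Their medians were 0.04 (adjusted p = 0.846), 0.12 (adjusted p = 0.846; the mean was -0.04 and the test's direction was up) and 0.10 (adjusted p = 0.547). The largest ratios were 0.14 for ITGAM, -1.02 for ROBO4 and 0.54 for ENO2. The rule for choosing list members took 81 that passed in the mean knockdown. Of these, 75 passed in most alternatives, 11 in all and 77 on slide 1 alone. With median centring 55 passed and 76 kept their sign. With the slide block or without the first shRNA replicate 1, 17 passed. The number was 43 without the first shRNA replicate 2, 14 without the second shRNA replicate 1 and 38 without the second shRNA replicate 2.

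**Figure D3:**
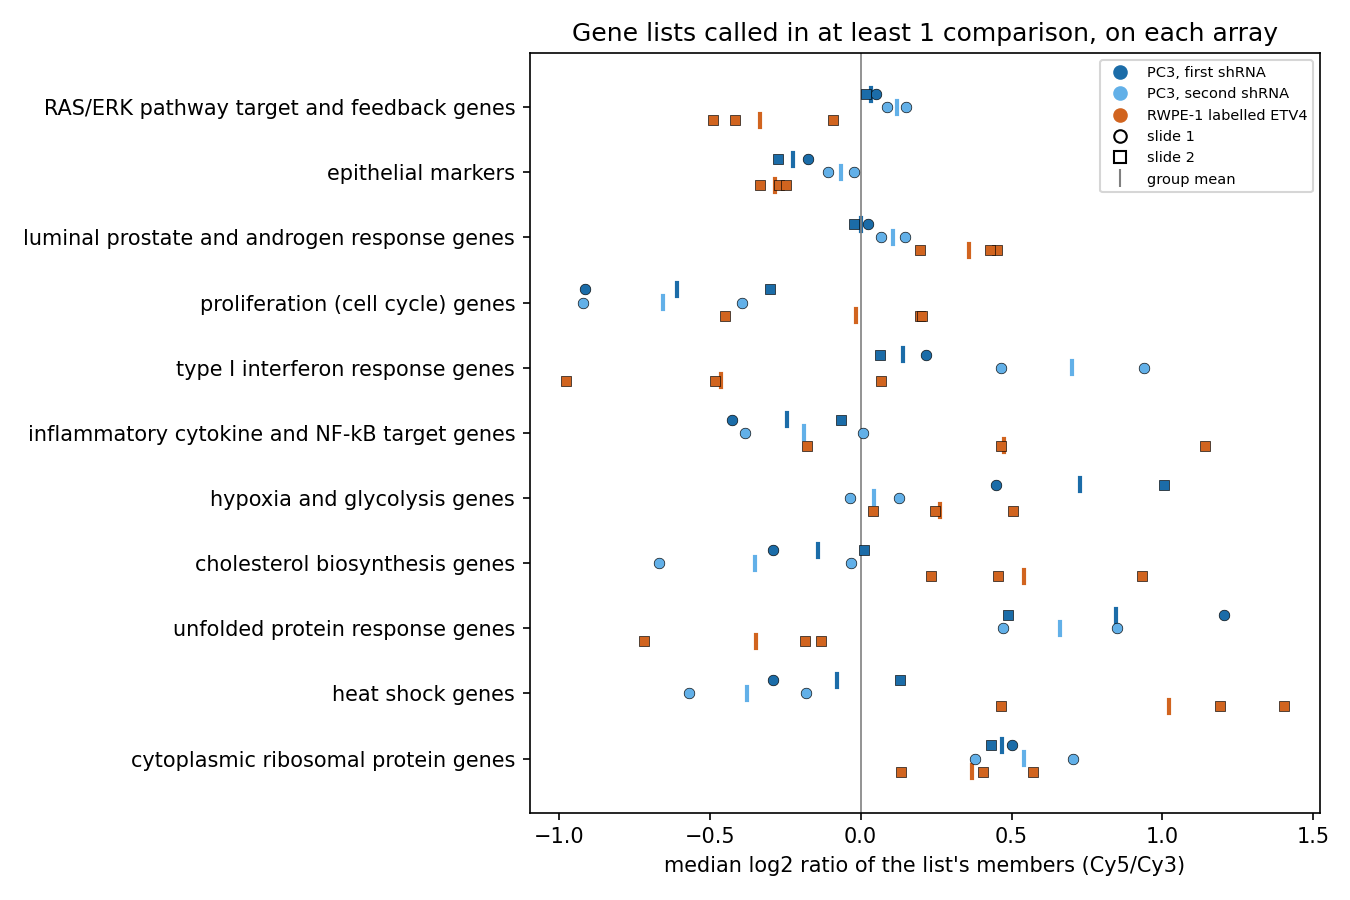
Median log2 ratio of treated over control cells over the measured members (horizontal axis) of the 11 gene lists called in at least 1 comparison (vertical axis); each point is 1 array, with symbols and colours as in the figure of the ETV probes. Ribosomal protein genes lie between 0.13 and 0.70 on all 7 arrays, and heat shock genes at 1.19, 1.40 and 0.47 on the RWPE-1 arrays; the medians of 2 called lists change sign with median centring, to 0.02 for cholesterol biosynthesis in PC3 and to 0.04 for epithelial markers in RWPE-1.

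On the RWPE-1 arrays labelled ETV4, where 1 ETV4 probe ran against the label, limma called 0 genes (smallest adjusted p = 0.0508). At an unadjusted p under 0.05 there were 5899, where 1160 were expected by chance, and 2465 had an adjusted p under 0.10, 1228 higher and 1237 lower. Without RWPE-1 replicate 3, 2499 genes passed. Other planned settings called 0, or between 110 with no background subtraction and 689 with median centring. With the slide as a block limma called 0. The genes with the largest ratios at an unadjusted p under 0.01 were chosen after their values were seen. The highest were PLAT, the tissue plasminogen activator (2.59, SD 1.82, n = 3, adjusted p = 0.0642), DEFB103B, a defensin (2.52, SD 2.31), and the chaperone HSPA8 (2.17, SD 1.39). The lowest were CH25H, a cholesterol hydroxylase (-1.82, SD 1.47), the netrin receptor UNC5B (-1.81, SD 0.99), and LURAP1L (-1.71, SD 0.71, adjusted p = 0.0508).

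Several gene lists shifted as a whole on the RWPE-1 arrays labelled ETV4, though 0 members of any list passed over all genes and 1 ETV4 probe ran against the label. Of the heat shock genes, which encode chaperones, 8 of 9 were higher when adjusted over the list alone, led by HSPA8 (2.17) and HSPA1A (1.73). They had a median of 0.97 (camera adjusted p = 3.66e-05, and adjusted p = 0.618 with an estimated correlation) and 0.77 with the slide block. Of 16 cholesterol biosynthesis genes, 6 were higher and 1 lower when adjusted over the list alone, with HMGCS1 at 1.28 and FDFT1 at 1.05. Their median was 0.60 (camera adjusted p = 6.17e-05, and adjusted p = 0.618 with an estimated correlation), 0.28 with the slide block and 0.30 without RWPE-1 replicate 1. Of 28 ribosomal protein genes, 15 were higher when adjusted over the list alone, with RPL35 at 0.74 and RPS14 at 0.71. The list's median of 0.39 (camera adjusted p = 1.23e-06, and adjusted p = 0.618 with an estimated correlation) stood beside 0.29 in random lists of equally bright genes and 0.39 in the 100 brightest genes. It was 0.42 with the slide block, 1.17 with median centring and 0.14 with the deposited log10 ratio, which ended the call (adjusted p = 0.153). Of 13 luminal prostate and androgen response genes, 5 were higher and 1 lower when adjusted over the list alone, with the protease TMPRSS2 at 1.62 and HOXB13 at 1.07. Their median was 0.19 (camera adjusted p = 0.0219, and adjusted p = 0.618 with an estimated correlation). The call ended with the slide block (0.23, adjusted p = 0.135), with median centring (0.64, adjusted p = 0.0557) and without RWPE-1 replicate 1 (0.15, adjusted p = 0.120) or 3 (0.45, adjusted p = 0.0558). The median was 0.49 with the deposited log10 ratio, 0.53 with signal required on all 7 arrays, 0.35 on slide 2 alone and 0.39 without RWPE-1 replicate 2.

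Lower lists on the same arrays included interferon response genes, of which 1 of 21 was lower when adjusted over the list alone. OASL stood at -1.41 and IFIT1 at -0.93. The median was -0.45 (camera adjusted p = 0.000605, and adjusted p = 0.618 with an estimated correlation), -0.47 with the slide block and -0.20 with median centring. Without RWPE-1 replicate 1 it was -0.22 and the call ended (adjusted p = 0.195), and without replicate 3 it was -0.73. Epithelial markers were lower, except that with median centring their median was 0.04 while the test's direction stayed down (adjusted p = 0.358). Of 18, 8 were lower when adjusted over the list alone, with the splicing regulator ESRP1 at -0.87 and E-cadherin (CDH1) at -0.77. Their median was -0.33 (camera adjusted p = 0.00163, and adjusted p = 0.618 with an estimated correlation; -0.16 with the slide block). Of 22 RAS/ERK targets, 1 was higher and 4 lower when adjusted over the list alone, with MYC at -1.31 (1 of its 2 other probes in the opposite direction) and PHLDA1 at -1.22. Their median was -0.25 (camera adjusted p = 0.00853, and adjusted p = 0.618 with an estimated correlation; -0.24 with the slide block). Leaving out RWPE-1 replicate 1 ended that call (-0.13, adjusted p = 0.195), and the median was -0.40 without replicate 3. None of 14 unfolded protein response genes passed when adjusted over the list alone, with the chaperone HSPA5 at -0.90 and the factor XBP1 at -0.85. The list's median was -0.38 (camera adjusted p = 0.0253, and adjusted p = 0.618 with an estimated correlation). The call ended with median centring (-0.04, adjusted p = 0.358) and without RWPE-1 replicate 2 (-0.16, adjusted p = 0.160) or 3 (-0.54, adjusted p = 0.0676). With the slide block the median was -0.06 and the test's direction turned up (adjusted p = 0.662).

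The other lists were not called on the RWPE-1 arrays labelled ETV4 with all arrays, and their counts are those higher and lower when adjusted over the list alone. ETS factors had 1 and 3 of 24 with ETS2 at -1.02 and ETV4 as given (median -0.07, adjusted p = 0.150). AP-1 genes had 0 and 1 of 11 with FOS at -0.57 (median -0.26, adjusted p = 0.0625). Proteases had 2 and 1 of 20 with the plasminogen activator PLAT at 2.59 (median 0.18, adjusted p = 0.295). Adhesion genes had 0 and 0 of 21 (median -0.11, adjusted p = 0.215). Mesenchymal markers had 1 and 3 of 14 with tenascin (TNC) at -0.93. The median of 0.06 was above 0, and the mean of -0.03 and the test were below (adjusted p = 0.865). Basal and squamous markers had 2 and 7 of 18 with KRT6B at 1.26 (median -0.07, adjusted p = 0.212). Proliferation genes had 1 and 0 of 29 with cyclin E1 (CCNE1) at 0.75 (median -0.08, adjusted p = 0.910). Inflammatory genes had 6 and 2 of 20 with ICAM1 at 1.42 (median 0.49, adjusted p = 0.110). The p53 targets had 0 and 0 of 16 (median 0.31, adjusted p = 0.163), and TGF-beta targets had 3 and 2 of 15 with CCN2 at 1.51 (median 0.15, adjusted p = 0.295). WNT targets had 2 and 1 of 12 with MYC at -1.31 (median 0.07 and test up, mean -0.04, adjusted p = 0.910). Hypoxia genes had 0 and 0 of 16 (median 0.21, adjusted p = 0.159). Angiogenic factors had 1 and 1 of 16 with IGFBP5 at 1.83 (median -0.12 and test down, mean 0.14, adjusted p = 0.865). Among other cell types, fibroblast markers had 0 and 0 of 8 (median 0.14, adjusted p = 0.282). Leukocyte markers had 0 and 0 of 5 (median -0.03, mean 0.11 and test up, adjusted p = 0.651). Endothelial markers had 0 and 1 of 6 with KDR at 1.00 (median 0.40, adjusted p = 0.295), and neuroendocrine markers had 1 and 1 of 5 with ENO2 at 0.99 (median 0.07, adjusted p = 0.824).

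Alternatives, all at the preset correlation, called 6 of these lists in RWPE-1. The p53 targets were higher with median centring (0.57, adjusted p = 0.0234) and without RWPE-1 replicate 3 (0.83, adjusted p = 0.000105). Hypoxia genes were higher with median centring (0.52, adjusted p = 0.00131) and without replicate 2 (0.23, adjusted p = 0.0241). Inflammatory genes were higher with signal required on all 7 arrays (0.66, adjusted p = 0.0428) and without replicate 1 (0.81, adjusted p = 0.000726). ETS factors were lower with signal required on all 7 arrays (-0.10, adjusted p = 0.0322), with the slide block (-0.08, adjusted p = 0.0392) and without replicate 3 (-0.14, adjusted p = 0.0401). AP-1 genes were lower with the slide block (-0.23, adjusted p = 0.0353) and without RWPE-1 replicate 2 (-0.33, adjusted p = 0.00566). Without the second shRNA replicate 1 or 2 they were at -0.26 and -0.27. As all RWPE-1 arrays lie on slide 2, the block's shift there comes from 2 PC3 arrays. With it proliferation genes were lower (-0.47, adjusted p = 0.00236), beside -0.45, 0.20 and 0.20 per array.

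The test of RWPE-1 minus PC3 asked which genes differed in ratio between introduced ETV4 in RWPE-1, as labelled, and knockdown in PC3. It called 1872 genes, 943 higher and 929 lower in RWPE-1, 276 and 284 of them by at least 2-fold (n = 3 and 4). The higher share was 50.4%, against 36.5% of 687 genes with median centring. The genes below had means of opposite sign, given as knockdown and then RWPE-1 value. The largest positive differences were those of TLR2 (-0.86 and 2.02, difference 2.88, SE 0.60, adjusted p = 0.0366), the transporter ABCA13 (-1.57 and 0.98), ANKRD22 (-1.23 and 1.13) and BIRC3 (-2.09 and 0.26, difference 2.35, SE 0.21, adjusted p = 0.00987). They were followed by GM2A (-0.70 and 1.63), LCP1 (-0.93 and 1.39), KRT34 (-1.31 and 1.00), SLC39A8 (-1.47 and 0.78), MARCHF4 (-1.37 and 0.87) and NEXN (-1.22 and 1.00). The largest negative ones were those of FST, an activin antagonist (1.27 and -1.30, difference -2.57, SE 0.61, adjusted p = 0.0475), ALDH2 (1.95 and -0.49, difference -2.44, SE 0.24, adjusted p = 0.0102), and LURAP1L (0.71 and -1.71). They were followed by MKX (1.45 and -0.79), NEBL (1.87 and -0.36), MAL2 (1.35 and -0.82), NPTX1 (2.11 and -0.04), IGF2 (0.76 and -1.37), complement component C5 (1.21 and -0.93) and SLC38A2 (0.80 and -1.32). ETV1 also differed (-1.31, SE 0.16, adjusted p = 0.0133). ETV5 (-1.19, adjusted p = 0.0503) and ETV4 by its second probe (0.57, adjusted p = 0.159) did not pass.

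Each of these 20 genes and ETV1 kept its sign with the slide block and on slide 2 alone, with absolute log2 differences of at least 1.35 and 1.31 for the 20. None of the 20 passed there, but slide 2 holds 1 knockdown array and the block rests on 1 pair of arrays. ETV1 stood at -1.22 (adjusted p = 0.700) with the block and at -1.45 (adjusted p = 0.776) on slide 2. Limma called 0 genes in all with the block or on slide 2 alone, against 6497 at an unadjusted p under 0.05 without it. Leaving out the first shRNA replicate 1 gave 2 genes, and leaving out its replicate 2 gave 510. Leaving out the second shRNA replicate 1 gave 12, its replicate 2 gave 11, and RWPE-1 replicate 2 gave 615. The direction of ETV4 in RWPE-1 rests on the label, since 1 probe ran against it. With the sign of the RWPE-1 arrays turned, the difference called 3223 genes, 1570 higher and 1653 lower. The 20 named genes would then have 1 sign in both lines, and 5 of them passed, with TLR2 at -1.16 (adjusted p = 0.227) and BIRC3 at 1.82 (adjusted p = 0.0108).

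Genes of cell division, which fell in PC3, were higher in RWPE-1 than in PC3 by this difference. Of 29, 10 passed as higher, 0 as lower and 19 did not pass, and 13 were higher when adjusted over the list alone, with CCNE1 at 1.41 and CDC25A, CCNE2 and MCM7 at 1.38. The median difference was 0.73 (camera adjusted p = 1.17e-05, and adjusted p = 0.774 with an estimated correlation) and 0.31 on slide 2 alone. The slide block ended the call (0.12, adjusted p = 0.103). Heat shock genes were higher for 5 of 9 and for 7 when adjusted over the list alone, with HSP90AA1 at 1.74, HSPH1 at 1.32, BAG3 at 1.31 and HSPE1 at 1.12. Their median was 1.31 (camera adjusted p = 1.72e-05, and adjusted p = 0.774 with an estimated correlation; 0.88 with the slide block and 0.89 on slide 2). Cholesterol biosynthesis genes were higher for 7 of 16 and for 9 when adjusted over the list alone, with HMGCS1 at 1.74, SQLE at 1.36, DHCR7 at 1.34 and MSMO1 at 1.23. Their median was 0.74 (camera adjusted p = 6.59e-06, and adjusted p = 0.774 with an estimated correlation; 0.53 with the slide block and 0.57 on slide 2). Of 20 inflammatory genes, 4 were higher, and 7 when adjusted over the list alone. The 4 were the cytokine CSF2 (1.90), TNFAIP3 (1.88), NFKBIA (1.58) and the chemokine CXCL5 (0.52). That list's median of 0.62 (camera adjusted p = 0.00773, and adjusted p = 0.774 with an estimated correlation) was 0.57 on slide 2. The call ended with the slide block (0.52, adjusted p = 0.0814) and without RWPE-1 replicate 3 (0.79, adjusted p = 0.129). It was 1.17 with the deposited log10 ratio, 1.16 with signal required on all 7 arrays and 0.98 without RWPE-1 replicate 1.

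Interferon response genes were lower by the difference for 4 of 21 and for 13 when adjusted over the list alone, with MX1 at -1.62, IRF9 at -1.60, IFI44L at -1.59 and IRF7 at -0.91. Their median was -0.87 (camera adjusted p = 6.59e-06, and adjusted p = 0.774 with an estimated correlation; -0.75 with the slide block and -0.63 on slide 2). Unfolded protein response genes were lower for 1 of 14 and for 11 when adjusted over the list alone. The 1 was EDEM1 (-0.73), named after its value was seen, and the largest ratios were those of ASNS (-1.77, adjusted p = 0.103, its 1 other probe in the opposite direction) and HERPUD1 (-1.59, adjusted p = 0.0536). The median difference was 2.15-fold toward lower values in RWPE-1 (camera adjusted p = 6.59e-06, and adjusted p = 0.774 with an estimated correlation), and on the log2 scale it was -0.66 with the slide block and -0.94 on slide 2. Ribosomal protein genes were lower for 1 of 28, RPLP0 (-0.59), and for 0 when adjusted over the list alone. The 100 brightest genes had a median of -0.17. The ribosomal median of -0.23 (camera adjusted p = 0.00773, and adjusted p = 0.774 with an estimated correlation) lost its call with the slide block (-0.14, adjusted p = 0.0608) and on slide 2 (-0.14, adjusted p = 0.0578). The call also ended with the deposited log10 ratio (-0.20, adjusted p = 0.0842), with median centring (-0.21, adjusted p = 0.115), and without the second shRNA replicate 1 (-0.16, adjusted p = 0.110) or RWPE-1 replicate 2 (-0.12, adjusted p = 0.1005).

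Lists not called in the difference with all arrays included proteases, of which 2 of 20 were higher and 3 lower (4 and 4 when adjusted over the list alone), with a median of 0.25 (adjusted p = 0.898). Among them MMP1 stood at -2.07 and SERPINB2 at 1.77. ETS factors had 0 higher and 2 lower of 24 (1 and 3 over the list alone), ETV1 and ELF1 (-0.72; median -0.05, adjusted p = 0.404). RAS/ERK targets had 0 and 1 of 22 (0 and 4), with PHLDA1 at -1.59, which did not pass (median -0.44, adjusted p = 0.0766). AP-1 genes had 0 and 1 of 11 by both adjustments, JUNB at -0.97 (median -0.26, adjusted p = 0.116). Adhesion genes had 0 and 2 of 21 (2 and 5), ITGA1 at -1.32 and ITGB4 at -1.04 (median -0.10, adjusted p = 0.430). Mesenchymal markers had 0 and 2 of 14 (0 and 3), TNC at -0.96 and FN1 at -0.95 (median -0.12, adjusted p = 0.350), and epithelial markers had 0 and 2 of 18 (1 and 2), CLDN7 at -0.71 and CDH1 at -0.69 (median -0.03, adjusted p = 0.446). Basal and squamous markers had 1 and 1 of 18 (1 and 6), with SFN at 0.84 the higher (median -0.16, adjusted p = 0.142). Luminal genes had 3 and 0 of 13 by both adjustments, among them STEAP1 at 1.36 and SLC45A3 at 1.26 (median 0.12, adjusted p = 0.215). Of 16 p53 targets FAS was higher (1.58) by both adjustments (median 0.14, adjusted p = 0.505). TGF-beta targets had 1 and 1 of 15 (2 and 1), with ID1 at -1.43 the lower (median 0.15, adjusted p = 0.350).

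In the same difference 0 of 12 WNT targets passed by either adjustment (median 0.03 and test up, mean -0.04, adjusted p = 0.841). Nor did any of 16 hypoxia genes (median -0.17, adjusted p = 0.215). Angiogenic factors had 1 and 0 of 16 (1 and 1 when adjusted over the list alone), CCN1 at 1.34 (median -0.16, adjusted p = 0.350). Among other cell types, fibroblast markers had 1 and 0 of 8 (1 and 1) (median 0.08, adjusted p = 0.837). Endothelial markers had 0 and 1 of 6 by both adjustments, CLDN5 at -0.65, named after its value was seen (median 0.26, adjusted p = 0.645). Leukocyte markers had 0 of 5 (median -0.03, mean 0.06 and test up, adjusted p = 0.864). Neuroendocrine markers had 0 of 5 (median -0.07, adjusted p = 0.713). Differences are not given for MMP13 and LUM, which were not well above background in RWPE-1, or for SPRR1B and CHGB, which were not in PC3, while the counts include them.

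Alternatives called 7 of these lists in the difference, also at the preset correlation alone. No p is given where a group keeps 1 array. RAS/ERK targets were lower with median centring (-0.46, adjusted p = 0.00259) and with the slide block (-0.40, adjusted p = 0.0259). They were also lower without RWPE-1 replicate 2 (-0.32, adjusted p = 0.0304) or 3 (-0.62, adjusted p = 0.0111). On slide 2 alone they stood at -0.30, and without the first or second shRNA replicate 1 at -0.41 and -0.40. AP-1 genes were lower with the slide block (-0.39, adjusted p = 0.0241), on slide 2 alone (-0.44) and without the second shRNA replicate 1 (-0.31). Hypoxia genes were lower with the slide block (-0.44, adjusted p = 1.25e-05), on slide 2 alone (-0.70) and without the first shRNA replicate 1 (-0.33). On PC3 arrays their medians were 1.00 on slide 2 and 0.45, 0.13 and -0.04 on slide 1. Mesenchymal markers were lower without RWPE-1 replicate 2 (-0.20, adjusted p = 0.0491). Angiogenic factors were lower on slide 2 alone (-0.39, against -0.16 with all arrays). Without RWPE-1 replicate 3, basal and squamous markers were lower (-0.13, adjusted p = 0.0459) and p53 targets higher (0.54, adjusted p = 0.00414).

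The direction of each list difference rests on the label of the RWPE-1 arrays. With their sign turned, proliferation genes were still higher (0.82, adjusted p = 9.37e-07) and ribosomal protein genes lower (-0.88, adjusted p = 9.28e-14). Heat shock (-0.55, adjusted p = 0.125) and cholesterol genes (-0.29, adjusted p = 0.376) changed to lower values and interferon genes to 0.06 (adjusted p = 0.807). These 3 lists, inflammatory genes (0.08, adjusted p = 0.798) and unfolded protein response genes (-0.45, adjusted p = 0.336) lost their calls. Epithelial markers (0.60) and hypoxia genes (-0.65) gained one (adjusted p = 0.00274 each). With an estimated correlation none was called (adjusted p = 0.816 for each called list). Of 54 list members that the same rule took as passing in this difference, 38 passed in most alternatives and 0 with the slide block or on slide 2 alone. The number was 1 without the first shRNA replicate 1 or the second shRNA replicate 1, 21 without the first shRNA replicate 2, 2 without the second shRNA replicate 2 and 28 without RWPE-1 replicate 2.

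Loss and gain of 1 factor were compared to ask which genes moved in opposite directions. With limma, 0 genes were called in both the mean knockdown and the RWPE-1 arrays labelled ETV4. Without RWPE-1 replicate 3, 739 genes were, 263 of them in opposite directions and 476 in the same direction. Median centring gave 416, 25 of them in opposite directions and 391 in the same. At an unadjusted p under 0.05, 2404 genes lay in both, 978 of them in opposite directions (1013 expected from independent lists) and 1426 in the same direction (1014 expected). The direction in 1 line depended on that in the other (Fisher's exact test, two-sided, p = 9.84e-20, odds ratio 2.12), across genes, which are not independent replicates. Of the 4534 genes called in the knockdown, 1991 (43.9%) had the opposite sign in RWPE-1, and 56.1% would with the RWPE-1 ratios turned. One sign on all 7 arrays was seen for 2912 genes and opposite signs on all 4 and all 3 arrays for 2152, where unrelated directions of the lines, given the agreement within each, would give 2435 and 2433. The mean ratios of the lines correlated at r = 0.0547 across genes. A dye effect of a probe that is the same on every array adds to same-direction counts.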

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

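Chosen only after the result was seen were the tests of a dye effect common to all arrays, of the size of the shared change in RWPE-1 and of the ETV4 probes, and the counts on slide 2 alone.

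In the test of the RWPE-1 value minus the mean knockdown value limma called 1872 genes. With the slide as a block, and on slide 2 alone, limma called 0 genes in that test, where the fit over both slides had 6497 at an unadjusted p under 0.05. Slide 2 holds 1 knockdown array, and the block rests on 1 pair of arrays, so these counts do not show equal ratios in both lines. The 20 genes named for this difference kept their signs, with absolute log2 differences of at least 1.35 with the block and 1.31 on slide 2. With the 7 arrays divided into 3 and 4 in a fit of 2 groups, the real division gave 2802 genes and the highest other 1. The share, 1 of 35 (0.0286), is the lowest possible and does not exclude chance. The division by slide gave 1 gene. For the mean knockdown (4534 genes, highest other sign assignment 0, 1 of 8 with as many) and for the RWPE-1 arrays (0 genes, highest other 0, 4 of 4 with as many) the sign assignments are too few to give a share under 0.05.

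Outside the log2 ratios, the Cy3 channel alone showed a signal at 1 probe without a gene name, A_32_P167111 (hg18, chromosome 3, 178891637 to 178891696, plus strand). Its mean brightness in Cy3 lay between 617 and 970 on the 4 arrays of slide 2, against 88.8 to 103 on slide 1 and 60.0 to 76.4 in Cy5. It followed the slide, since slide 2 holds a PC3 array as well as the RWPE-1 arrays, and no explanation was tested.

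No gene passed on the 3 RWPE-1 arrays by limma, against 4534 on the 4 PC3 arrays, with 5899 at an unadjusted p under 0.05 in RWPE-1. The median SD of replicate spots, 0.0576 in RWPE-1 and 0.0301 in PC3, had a ratio of 1.91, as technical noise would give. The unshared RWPE-1 SD of 0.350 exceeded spot noise but may hold other technical noise. Without RWPE-1 replicate 3, 2499 genes passed, as 1 discordant array would give. However, that array had the highest weight of the 3 (0.701, against 0.476 and 0.607), and the fit with array weights called 0 genes. It correlated with replicate 2 at 0.389 and with replicate 1 at 0.116, beside 0.436 between those 2, so a discordant replicate 3 cannot be told apart from a spread over the arrays. The change shared by the arrays of a line had an SD over genes of 0.235 in RWPE-1 and 0.318 in PC3, a ratio of 0.739, while the unshared SDs were 0.350 and 0.208, so a smaller response cannot be told apart from a larger spread. Each explanation stays open. So does a biological difference between losing ETV4 in a cancer line and gaining it in an epithelial line, which was not tested.

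The 2 ETV4 probes moved apart on the RWPE-1 arrays labelled ETV4. Their mean difference of 1.24 (SD 0.35, n = 3) was 21.5 times the SD of replicate spots, which argues against spot noise. The second probe, which was lower, had 0 open reading frames and the first had 2, which is consistent with an introduced construct that lacks the end of the transcript the second probe lies in, and the second probe may then report only the cells' own ETV4. A dye swap would turn both probes, not move them apart. The first probe was above 0 on 3 of 3 arrays without passing (limma adjusted p = 0.111) and the second below 0 on each. A swap against the labels stays open. No biological explanation of the lower second probe was tested.

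Ribosomal protein genes were higher in Cy5 on each of the 7 arrays, with list medians of 0.13 to 0.70. Among 10000 random lists of equally bright genes the list lay at the percentile 88.3 in the mean knockdown and 91.7 in RWPE-1, which is in line with a dye trend of bright probes. The mean of the list medians was 0.50 (SD 0.14, n = 4) in PC3 and 0.37 (SD 0.22, n = 3) in RWPE-1, a difference of 0.927 standard errors, which is in line with a dye effect that is the same on every array. Without a dye swap both explanations, and a rise of these transcripts in both lines, stay open.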

How the results depend on the processing

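Chosen after the data were seen were the slides alone, the slide block read at slide 1 or at slide 2, the threshold of 0.10, and the use of the slide block for genes and lists, and the midpoint reading of the planned slide block was chosen after counts under another coding had been seen. The difference between the shRNAs stayed at 0 genes by limma in every setting run, with 568 at an unadjusted p under 0.05. Counts within 1.5 times of the reported ones came from Aquantile, a filter on all 7 arrays and the mean of the probes. No background subtraction gave 2291 genes for the first shRNA, 110 for RWPE-1 and 47 shared by knockdown and RWPE-1. The deposited log10 ratio and the series table gave 15 for the second shRNA, 115 for RWPE-1, 1237 for RWPE-1 minus knockdown and 35 shared. Median centring gave 624 and 3460 for the first and second shRNA, 689 for RWPE-1 (91.4% higher), 687 for RWPE-1 minus knockdown and 416 shared, and the largest median of all genes over the settings was 0.187. Loess and scale gave 4371 for the first shRNA and 0 for the second. No filter gave 396 for RWPE-1 and 127 shared. Testing all probes gave 511 for the second shRNA, 457 for RWPE-1 and 152 shared. Fits of each line alone gave 3582 and 2685 for the shRNAs and 7497 for the mean knockdown, and no value for RWPE-1 minus knockdown. Array weights gave 4754, 3522 and 7978 for the same 3, and the intensity trend gave 142 for RWPE-1 and 39 shared. A minimum of 1.5-fold left 1711 for the mean knockdown, and the threshold of 0.10 gave 2853 and 2076 for the shRNAs, 2465 for RWPE-1, 4074 for RWPE-1 minus knockdown and 935 shared. With the slide block the counts were 381 (63.8% higher), 1, 352 (64.2% higher) and 0 for the shRNAs, the mean knockdown and RWPE-1 minus knockdown. Read at slide 1 they were 1, 28, 1977 and 0, and at slide 2 they were 1, 0, 0 and 0. Slide 1 alone gave 3304 for the second shRNA, and slide 2 alone gave 0 for the first shRNA and 0 for RWPE-1 minus knockdown. The cause was not tested for any of these, except that a slide alone holds fewer arrays and that the block gives the mean knockdown the estimates it has without the first shRNA replicate 1. Leaving out 1 array at a time gave 1 to 1898 genes for the first shRNA, 0 to 951 for the second, 352 to 5686 for the mean knockdown, 0 to 0 for the difference of the shRNAs, 0 to 2499 for RWPE-1, 2 to 2326 for RWPE-1 minus knockdown and 0 to 739 shared. Where that left 1 array for a shRNA, the lone array is assumed to vary like the other groups. The replicate block gave 890, 348, 4204, 0 and 1358 genes for the shRNAs, the mean knockdown, the difference of the shRNAs and RWPE-1 minus knockdown, each within 1.5 times of the count without it. Same-numbered PC3 arrays correlated at r = 0.525 in their deviations across genes over 2 pairs, too few to treat the numbers as a pairing. Over settings other than leaving out an array, values of the 25 fixed lists kept their side of the threshold and sign 425 times, changed sign without a call 44 times, lost a call 34 times, gained one 21 times and reversed 1 time, for unfolded protein response genes in RWPE-1 with the slide block (-0.056). Of the added lists, the proteasome reversed in the mean knockdown with median centring (0.33). Values of named genes kept both 2712 times, changed sign without a call 5 times, lost a call 426 times, gained one 98 times and reversed 5 times, all with median centring in the mean knockdown: CCND1 0.12, HSPD1 0.32, PSMA3 0.17, PSMA1 0.059 and PSMB6 0.23. On leaving out an array, fixed lists kept both 460 times, changed sign without a call 31 times, lost a call 12 times and gained one 22 times, and named genes 1557, 6, 653 and 64 times. Turning the sign of the 3 RWPE-1 arrays, also chosen after the data were seen, gave 3223 for RWPE-1 minus knockdown (48.7% higher). With the deposited log10 ratio another probe stood for SCARA5 and gave 0.21.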

Other observations

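The 4 gene lists here, the test of ETV1 and ETV5 and the genes named as such were chosen after the values were seen. The lists' p-values only describe these data, and no list was run with the RWPE-1 sign turned.

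Trefoil factors, small secreted proteins of mucous epithelia, rose with ETV4 knockdown in PC3: TFF3 stood at 1.98, TFF2 at 1.73 and TFF1 at 1.43. Of 10 trefoil factors and mucins, these 3 rose and 0 fell, also when adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.00223, and adjusted p = 0.179 with an estimated correlation; 0.18 with the slide block and 0.23 on slide 1 alone). Of 14 proteasome subunits, 5 fell and 0 rose by both adjustments, with PSMA2 at -0.61, PSMA3 at -0.51, PSMA1 at -0.49 and PSMB6 at -0.43. Their median was -0.25 (camera adjusted p = 0.00140, and adjusted p = 0.439 with an estimated correlation), -0.13 with the slide block or without the first shRNA replicate 1 and -0.32 on slide 1 alone, but 0.33 and higher by the test with median centring (adjusted p = 0.0126). Of 15 circadian clock genes, PER3 (0.57), NR1D2 (0.56) and TEF (0.46) rose and CRY2 (-0.27) fell, by both adjustments, and the list was not called (median 0.30, adjusted p = 0.126). It was called as higher with median centring (0.38), on slide 1 alone (0.26), and without the second shRNA replicate 1 (0.29) or RWPE-1 replicate 2 (0.30). Of 16 aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, VARS1 fell (-0.44), 0 passed when adjusted over the list alone, and GARS1 and CARS1 stood at 0.49 each. That list's median was 0.05 and not called (adjusted p = 0.809), but 0.58 and called as higher with median centring (adjusted p = 0.0126).

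On the RWPE-1 arrays labelled ETV4, where 1 ETV4 probe ran against the label, aminoacyl-tRNA synthetases were lower. Of 16, 0 passed over all genes and 6 were lower when adjusted over the list alone, with IARS1 at -0.88 and AARS1 at -1.08 (median -0.51, camera adjusted p = 2.42e-05, and adjusted p = 0.339 with an estimated correlation; -0.43 with the slide block, -0.26 without RWPE-1 replicate 2 and -0.18 with median centring). Of 15 clock genes, 0 passed over all genes and 1 was higher and 8 were lower when adjusted over the list alone, with TEF at -1.17 and PER3 at -1.13. Their median was -0.47 (camera adjusted p = 0.000160, and adjusted p = 0.236 with an estimated correlation), -0.42 with the slide block and -0.31 without RWPE-1 replicate 1. Proteasome subunits (1 of 14 higher and 0 lower when adjusted over the list alone, PSMA6 at 0.55 and PSMA7 at 0.53, median 0.09, adjusted p = 0.0538) were not called. They were called as higher with median centring (0.53, adjusted p = 1.92e-10), without RWPE-1 replicate 1 (0.14, adjusted p = 0.00565) and without the first shRNA replicate 1 (0.09, adjusted p = 0.0494). Trefoil factors and mucins were not called either, and none of them passed (MUC20 at 0.46, median 0.15, adjusted p = 0.182). The probe that stood for TFF1 had a control channel not well above background in RWPE-1, and where signal on all 7 arrays was required its other probe gave 0.0062 (adjusted p = 0.981).

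By RWPE-1 minus knockdown, clock genes were lower for 4 of 15 and for 8 when adjusted over the list alone, with PER3 at -1.70, TEF at -1.63, NR1D2 at -1.28 and PER1 at -0.89, whose 1 other probe ran in the opposite direction. Their median was -0.54 (camera adjusted p = 0.000234, and adjusted p = 0.220 with an estimated correlation), -0.50 with the slide block, -0.61 on slide 2 and -0.89 without RWPE-1 replicate 2. Of 16 aminoacyl-tRNA synthetases 3 were lower, and 1 was higher and 9 lower when adjusted over the list alone, among them AARS1 (2.83-fold lower) and IARS1 (-0.91). Their median was -0.67 (camera adjusted p = 0.00104, and adjusted p = 0.282 with an estimated correlation), -0.44 with the slide block and -0.36 on slide 2. Of 14 proteasome subunits, PSMA7 was higher (0.68) beside PSMA6 at 0.81, and 7 were higher when adjusted over the list alone (median 0.44, camera adjusted p = 6.35e-05, and adjusted p = 0.220 with an estimated correlation; 0.23 with the slide block and 0.28 on slide 2). Trefoil factors and mucins were lower for 3 of 10 by both adjustments, with TFF3 at -1.90 and TFF2 at -1.60. The third was TFF1, for which the other probe gave -1.73 where signal on all 7 arrays was required (adjusted p = 0.00934). Their median was -0.13 (camera adjusted p = 0.0360, and adjusted p = 0.220 with an estimated correlation), -0.08 with the slide block and -0.11 on slide 2, and the call ended without RWPE-1 replicate 1 (-0.05, adjusted p = 0.0834) or 3 (-0.15, adjusted p = 0.106).

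A hypothesis from the knockdown was that the other PEA3 subfamily members, ETV1 and ETV5, move against ETV4. On the RWPE-1 arrays 1 of their 6 values was above 0, but since 1 ETV4 probe was lower and the other higher on these arrays, the test does not settle it.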
